A study of Arabidopsis thaliana with 7 samples.

How the data were processed

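Messenger RNA levels were measured on 7 one-colour ATH1 arrays of young rosette leaves from 14-day-old Arabidopsis plants of the Columbia background. Per the labels, the plants carried the transcription factor MYB46 under a promoter that dexamethasone (DEX) switches on. Plants were sprayed with 10 µM DEX, a synthetic steroid, together with a surfactant. Per the labels' protocols, control plants received the surfactant in water in relevant experiments; which arrays this covers is not given in the sources used here. Leaves without DEX were taken at 0, 1, 3 and 6 h, and leaves with DEX at 1, 3 and 6 h. Each of the 7 conditions had 1 array, so there are no biological replicates, and no array of DEX-treated plants lacking the construct was used here.

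The deposited values were linear intensity signals of 22810 probe sets per array, which the authors made with MAS5 per the submitters' processing notes; the version and the background settings are not given in the sources used here. The deposited intensity values were scaled array by array: without the highest and lowest 2% of probe sets, the mean signal was 500 on each of the 7 arrays. Array medians ran from 149.7 to 155.8 without DEX, and were 157.2, 170.8 and 175.5 with DEX at 1, 3 and 6 h. The number of arrays limits the precision.

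Control probe sets (64) were left out, and 22746 were analysed. Genes were named from the platform annotation table, with symbols and synonyms from a gene table of the TAIR10.1 assembly used for names only. The annotation gave 1 gene for 13513 probe sets, several for 503 and none for 8730; 13436 of those with 1 gene were found in the gene table. Probe sets with several genes or none were not named. A probe set missing from the annotation is unnamed here, not without a gene. MYB46 had no named probe set in these tables, nor had the secondary wall cellulose synthases or the NAC regulators of the secondary wall, so they were not analysed here. Of 270 genes on 25 lists fixed beforehand, 33 had a named probe set.

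Values were taken as log2(signal + 32), where 32 is the 25th percentile of all signals rounded to a whole number. Fold differences are on this scale and understate the difference of dim probe sets. Array medians on the log2 scale lay within 0.3 of each other, so the authors' scaling was kept. At each time, the array with DEX was compared with the array without DEX of the same hour. A probe set was counted as higher or lower when the difference was at least 2-fold and the value with DEX also lay outside the range of all 4 arrays without DEX. It was counted only where 1 of the 2 arrays compared was above its own median. The same rule, with the range of the 3 other arrays, was applied to the 12 ordered pairs of arrays without DEX. This shows how many probe sets differ between different hours with no inducer.

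limma 3.58.1 in R 4.3.3 was fitted to the 6 arrays of 1, 3 and 6 h with the time point as a block, once for a DEX effect common to the 3 times and once for an effect that grows in proportion to the hours. Both fits had 2 residual degrees of freedom, tested 13088 probe sets with 1 array above its median, and used Benjamini-Hochberg adjustment at 0.05. An effect that differs between times counts as error in these fits. The error is how far the DEX differences depart from the fitted effect across the 3 times, smoothed by limma over probe sets. With 1 array per condition, a p-value does not measure the spread between replicate plants.

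A gene was represented by its probe set of highest mean. For a list with at least 3 measured genes, the median log2 ratio was given with its percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. camera in limma tested the lists on the common effect with a preset correlation of 0.01 and with an estimated one. Of the 25 fixed lists, 5 had at least 3 measured genes. A further 16 lists were therefore defined after the annotation had been read and before any ratio was computed: loci commonly co-expressed with secondary wall genes, 13 gene families taken by symbol, and the plastid-encoded and mitochondrion-encoded genes.

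Named genes followed a rule set before the data were examined: MYB46; at 6 h the 12 highest and 8 lowest ratios among probe sets past the size rule with 1 gene, at 3 h the 10 highest and 6 lowest, and at 1 h the 8 highest and 4 lowest; the 10 smallest p-values of each limma fit; up to 4 genes of each fixed list; and the 3 highest and 3 lowest ratios of 6 h over 0 h without DEX. Other genes named were chosen after their values were seen, among them those of the added lists that were past the size rule: TBL30, TBL37, TBL28, scpl20, scpl48, GH9B18, GH9B7, TUB6, EXPB3, IQD22, AT3G42950 and AT4G27435.

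The limma fit and the size rule were tested on simulated data, with noise as in the common-effect fit, 13088 probe sets and 200 changed in each of 20 simulations. For changes of 2, 4 and 8-fold, the fit recovered 35.7%, 96.0% and 99.2%, and the size rule 53.4%, 99.2% and 99.8%. Unchanged probe sets called averaged 14.8 per simulation for the fit and 256.1 for the size rule. These shares hold for an effect equal at all 3 times. The noise was drawn from limma's variances after shrinkage toward a common value, with no change between hours. The shares are therefore not the power of the real fit. There 250322_at, with a log2 effect of 6.16, had an adjusted p of 0.104 in limma.

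Alternatives covered the log offset, quantile normalisation and median centring, the signal filter, the size threshold, the range condition, the comparator, the time block, each time pair left out, the prior of the fit and the p threshold. Leaving out the array without DEX at 3 h was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.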

Results

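The data were transcript levels in young rosette leaves of Arabidopsis plants in which DEX switches on MYB46, a MYB transcription factor that activates secondary wall formation. Leaves were sampled without DEX at 0, 1, 3 and 6 h (4 arrays) and with DEX at 1, 3 and 6 h (3 arrays). There were no replicates, so the values below are single measurements and the ratios at a single time carry no test. Arrays of the same hour with and without DEX correlated at 0.976, 0.951 and 0.964 at 1, 3 and 6 h, across probe sets, which are not independent replicates. MYB46 itself had no named probe set and was not analysed here.

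The first comparison asked which genes differed within 1 h of DEX. AT5G05320 was 8.72-fold higher with DEX, with a signal of 1256 against 115.7, and remained 6.16-fold higher at 3 h and 4.47-fold higher at 6 h. AT2G36220 was 8.56-fold higher, AT1G75860 4.80-fold and AT5G47060 4.26-fold. XTH19, which remodels xyloglucan in the primary wall, was 4.03-fold higher at 1 h and within the no-DEX range at 3 and 6 h. The thaumatin-like gene AT1G20030 was 3.93-fold higher, AT1G32780 3.39-fold and AT3G44630 3.17-fold. The lowest values were those of AT5G53770, with a log2 ratio of -2.41, AT3G61100 (-1.46), AT1G48570 (-1.39) and AT4G29020 (-1.34). AT5G53770 read 6.65 with DEX, near the median of the bacterial control probe sets on that array (6.29), so the offset sets the size and rank of its ratio. None of the measured xylan genes was past the size rule at this time, with log2 ratios from -0.28 to 0.29.

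In all, 124 probe sets were higher and 46 lower at 1 h, of 11902 tested. The highest ratio, 53.7-fold, belonged to the unnamed probe set 250322_at, whose signal was 5491 with DEX and between 53.2 and 70.8 on the arrays without DEX. The unnamed probe set 265672_at was 22.8-fold higher, and 258589_at was the lowest, with a log2 ratio of -2.77. Between pairs of arrays without DEX, the same rule counted 407 to 1367 probe sets with a median of 843, against 178 to 312 at 1 h with ranges of equal size. The number of probe sets at 1 h was therefore below that between arrays without DEX. Those pairs all compare different hours, so their counts include changes over time. They do not give the noise within an hour.

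At 3 h, 3 of 4 measured genes for the synthesis of xylan, the main hemicellulose of secondary walls, were higher with DEX. The xylan list held 20 genes, and only these 4 had a named probe set. GUT1, a xylan synthase subunit, was 8.91-fold higher (signal 4283 against 452.4), the xylan gene IRX15-L 11.6-fold and the xylan synthase subunit GUT2 2.63-fold. IRX15 was not, with a signal of 5.18 against 9.61 and a log2 ratio of -0.16. Both signals lay below the 75th percentile of the bacterial control probe sets on their arrays (13.2 and 12.7). This probe set therefore cannot show whether IRX15 changed. AT1G66810, whose synonym is C3H14, encodes a zinc finger regulator and was 3.45-fold higher. Among the highest ratios of all named genes were AT4G39320 at 43.3-fold, AT3G17130 at 29.4-fold, the receptor-like kinase NCRK at 26.9-fold, AT5G06930 at 24.2-fold and AT1G03920 at 23.9-fold.

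The peroxidase gene AT4G26010 was 21.1-fold higher at 3 h, AT4G24130 17.8-fold, AT1G70985 15.5-fold, AT5G47060 15.5-fold and AT4G17280 15.4-fold. AT4G26010 read 673.0 with DEX and 1.38 without, below the median of the bacterial control probe sets on that array (4.69), so the size of its ratio and its rank are set by the offset, as are those of NCRK and AT1G70985, which read 3.21 and 8.16 without DEX. AT1G70985 had read 155.1 and 171.1 without DEX at 0 and 1 h, so its ratio also holds a fall without DEX. AT1G22410, which encodes an enzyme of the first step of the shikimate pathway, was 2.42-fold higher. TUB6, a beta-tubulin, was 2.93-fold higher, TBL30 6.49-fold, scpl20 4.59-fold, scpl48 3.40-fold, GH9B18 3.44-fold and GH9B7 2.26-fold.

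The lowest named ratios at 3 h were those of AT2G20670 (log2 ratio -4.34), AT2G18210 (-3.70), AT2G26190 (-3.26), the brassinosteroid-responsive gene EXO (-3.12), AT4G34150 (-2.97) and AT1G56520 (-2.92). For each of these 6 genes the array without DEX at 3 h held the highest of the 4 no-DEX signals, such as 1704 for EXO against 185.9 to 550.8 on the other 3. Relative to the mean of those 3 arrays, the log2 difference of the DEX array was -2.37 for AT2G20670, -0.91 for AT4G34150, -0.74 for AT1G56520, -0.65 for EXO, -0.30 for AT2G26190 and -0.13 for AT2G18210. AT2G18210 and AT1G56520 read 2.40 and 12.35 with DEX at 3 h, below the 75th percentile of the bacterial controls on that array (13.2), so the offset sets the sizes and ranks of their ratios. TBL37 and TBL28 were also lower, with log2 ratios of -1.06 and -1.11.

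Across all probe sets, 656 were higher and 213 lower at 3 h, of 12130 tested. With no range condition, 737 were at least 2-fold higher and 750 at least 2-fold lower. Of the 656 and 213, 455 and 89 were also counted without the array lacking DEX at 3 h, an alternative added after the data were seen. With ranges of equal size, 924 to 946 probe sets were counted, within the 407 to 1367 between arrays without DEX of different hours. The share of higher calls was 75.5%, and 63.5% after median centring.

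**Figure D1:**
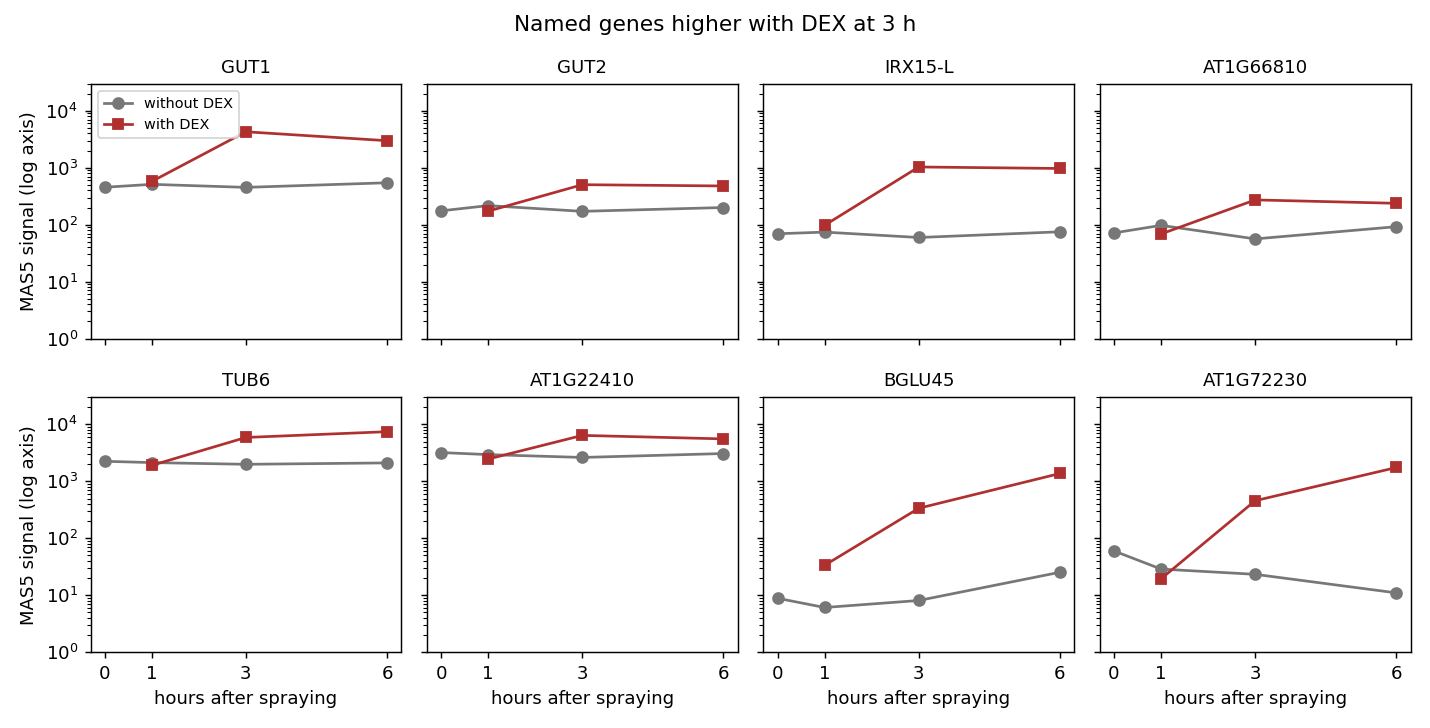
MAS5 signal on a log axis against hours after spraying for 8 named genes, with grey circles for arrays without DEX and red squares for arrays with DEX; each point is 1 array. GUT1 reads 574.0 with DEX at 1 h, 4283 at 3 h and 2987 at 6 h, against 452.4 to 544.9 without DEX.

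At 6 h, the same xylan genes were again higher: IRX15-L was 9.37-fold higher, GUT1 5.23-fold and GUT2 higher by 1.14 on the log2 scale, and AT1G66810 was 2.17-fold higher. With the offset of 32, the highest named ratio was that of AT1G72230, a copper-binding cupredoxin gene, at 41.5-fold, with a signal of 1754 against at most 60.0 on the arrays without DEX. AT3G45710, of the nitrate and peptide transporter family, was 37.9-fold higher, NCRK 37.8-fold, AT4G39320 34.1-fold, AT5G06930 30.5-fold and AT2G27740 30.3-fold. BGLU45, a beta-glucosidase acting on monolignol glucosides, was 24.6-fold higher, and CP1, a cysteine protease gene, 14.9-fold.

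AT1G70985 was 26.8-fold higher at 6 h, AT4G17280 23.2-fold, AT1G64405 18.6-fold and AT4G24130 15.2-fold. NCRK, AT3G45710 and AT1G64405 read 2.65, 3.73 and 3.71 without DEX at 6 h, AT1G72230 read 11.02 and AT1G70985 12.33, so the sizes and ranks of their ratios are set by the offset. The ratio of AT1G70985 also holds a fall without DEX, from 155.1 and 171.1 at 0 and 1 h. TUB6 was 3.50-fold higher, with a signal of 7460 against 1996 to 2255 on the 4 arrays without DEX. AT1G22410 was 1.80-fold higher, below the size rule. UGT76B1 was 7.84-fold higher, scpl20 2.95-fold and the expansin gene EXPB3 2.33-fold.

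Lower at 6 h was AT5G61590, whose synonym is DEWAX and which represses wax synthesis, with a log2 ratio of -2.43 (signal 346.4 against 2013). AT4G18970 (-2.19), AT5G12940 (-2.05), AT1G23390 (-1.84), AT2G30930 (-1.80), the lipase gene AT1G29660 (-1.79), AT5G19120 (-1.79) and the methionine sulfoxide reductase gene MSRB6 (-1.71) followed. The ratio of AT5G12940 is also set by the offset, as it read 18.3 with DEX, within the signals of the bacterial controls on that array.

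In total 448 probe sets were higher and 120 lower at 6 h, of 12029 tested. With ranges of equal size the count was 581 to 591, again within that between arrays without DEX of different hours. The share of higher calls was 78.9%, and 68.6% after quantile normalisation and 60.4% after median centring, which moved the median ratio of the tested probe sets from 0.01 to -0.15 (log2). The DEX array at 6 h also held a higher low end of signals, with a 25th percentile of 44.8 against 26.2 to 34.7 on the other 6 arrays.

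**Figure D2:**
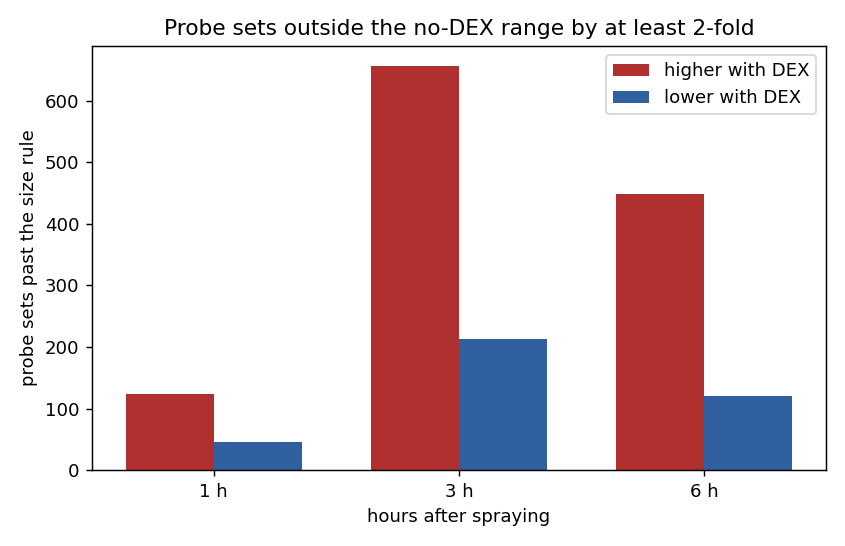
Number of probe sets past the size rule against hours after spraying, with red bars for those higher with DEX and blue bars for those lower. The 3 h comparison has the most, 656 higher and 213 lower, and each bar rests on 1 array with DEX.

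The question across times was whether the same genes differed at 3 and 6 h. Of the probe sets tested at both, 262 were higher at both times, where 17.8 are expected of independent lists, and 44 were lower at both, where 1.90 are expected. These named genes included GUT1, GUT2, IRX15-L, NCRK, BGLU45, TUB6, AT4G39320 and AT1G72230 among those higher, and AT5G61590, AT1G23390 and AT1G29660 among those lower. The range condition uses the same 4 arrays without DEX at each time. Unchanged arrays simulated against them shared 11.4 higher and 17.6 lower calls on average. They were drawn around the mean of those 4 arrays with the spread between their hours, not around the array of the same hour. Differences between hours thus entered as noise, so these counts are not those of unchanged arrays of the same hour. The log2 ratios correlated across probe sets at 0.65 between 3 and 6 h, with a covariance of 0.25 against -0.0093 simulated. The simulated DEX arrays were drawn independently of each other, so this contrast covers only the shared arrays without DEX. It leaves open other features that the DEX arrays share.

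Sharing with 1 h was smaller in number. Of those tested at both times, 27 probe sets were higher at 1 and 3 h and 22 at 1 and 6 h. Of independent lists, 4.47 and 1.82 are expected. Unchanged arrays simulated in the same way, with differences between hours as noise, shared 9.46 and 8.63 on average, and at most 18 and 16. Lower at both were 3 probe sets at 1 and 3 h and 1 at 1 and 6 h. Here 0.67 and 0.42 are expected of independent lists, and the simulation gave 19.9 and 10.1 on average. The ratios correlated at -0.19 between 1 and 3 h and at -0.0047 between 1 and 6 h. Higher at all 3 times were 19 probe sets, among them AT5G05320, AT5G47060, AT5G57070, AT1G32780, AT1G17620, AT5G52810, AT5G56980 and MYBC1. AT5G56980 was chosen after its values were seen.

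For a DEX effect common to the 3 times, AT5G05320 had the smallest p of the named genes, with a log2 effect of 2.64 ± 0.23 (SE), higher in 3 of 3 pairs, and an adjusted p of 0.337 in limma. AT5G57070 (1.59 ± 0.15, SE), AT1G32780 (1.58 ± 0.16), MYBC1 (ratios of 1.66, 2.71 and 1.92), AT1G20030 (2.87 ± 0.36), AT1G17620 (1.22 ± 0.15), AT5G52810 (1.47 ± 0.19), the peroxidase gene AT2G37130 (1.55 ± 0.20) and the thaumatin-like gene AT4G36010 (1.11 ± 0.16) came next, with adjusted p from 0.354 to 0.571. AT1G20030 read 3.37 without DEX at 6 h, below the median of the bacterial controls on that array (5.84), so its effect depends on the offset. Its signal with DEX at 6 h, 443.1, lay inside the range of the arrays without DEX. AT4G29020 was the first named gene on the lower side, at -1.16 ± 0.17 (SE) with an adjusted p of 0.580. In limma 0 probe sets passed 0.05; 640 were higher and 293 lower at an unadjusted p under 0.05, where 654.4 in all are expected by chance. The smallest adjusted p was 0.104, for the unnamed 250322_at and 265672_at.

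Without the 1 h pair, 103 probe sets rose and 6 fell in the same limma fit, with 1 residual degree of freedom. The size rule at 3 and 6 h uses the same differences, so its overlap with this fit is not separate support. Of the 103, 92 were also higher by the size rule at both 3 and 6 h. Among them were IRX15-L (log2 effect 3.38, adjusted p 0.0193 in limma), GUT1 (2.77, 0.0427), AT4G39320 (5.26, 0.0182), AT5G06930 (4.76, 0.0182) and NCRK (4.99, 0.0182). GUT2 had an effect of 1.27 and an adjusted p of 0.0924. These genes were chosen from the named ones after their values were seen.

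For an effect growing with the hours, AT2G27740 was the named gene with the smallest p, at 0.79 ± 0.05 log2 units per hour (SE), with ratios of 0.38, 2.14 and 4.92 at 1, 3 and 6 h. BGLU45 (0.83 ± 0.06 per hour, SE), the glycosyltransferase gene AT3G18170 (0.63 ± 0.05), UGT76B1 (0.50 ± 0.04), AT3G45710 (0.95 ± 0.08) and AT5G60720 (0.39 ± 0.04) followed, each with an adjusted p of 0.148 in limma. AT3G18170 read 5.27 without DEX at 6 h, so its effect also depends on the offset. The dehydrin gene LTI30 (0.47 ± 0.04) had 0.149. AT5G61590 had an adjusted p of 0.148 on the lower side (-0.41 ± 0.04, SE), and AT4G21865 (0.46 ± 0.04) and AT1G72230 (0.90 ± 0.09) had 0.166. No probe set passed 0.05 in limma (count 0); 836 were higher and 390 lower at an unadjusted p under 0.05.

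The gene lists asked whether wall pathways differed as groups. Of 20 genes on the xylan list, 4 had a named probe set. Among these 4, 0 were past the size rule at 1 h and 3 were higher at both 3 and 6 h (GUT1, GUT2 and IRX15-L). IRX15 read 44.0 with DEX at 6 h against 3.83, at the low end of the signals. The xylan list's median log2 ratio was 0.10 at 1 h (percentile 69.1 of random lists), 2.28 at 3 h and 1.76 at 6 h, both above all 10000 random lists. In camera on the common effect, the list had an adjusted p of 0.0712 over 21 lists, and an adjusted p of 0.849 with an estimated correlation. Without the 1 h pair, camera with the preset correlation gave an adjusted p of 7.0e-04. Without the 3 h pair it gave 0.146, and without the 6 h pair 0.354. The estimated correlation among the 4 genes was 0.60, and it was not used with a pair left out. No xylan gene passed limma's threshold on the common effect when adjusted over the list alone (count 0), nor over all probe sets tested.

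Of 15 measured loci commonly co-expressed with secondary wall genes, 2 were higher at 3 h and 4 at 6 h. The latter were AT1G72230, AT5G60720 at 5.04-fold, AT3G42950 at 4.59-fold and AT4G27435 at 2.74-fold; the list's median was -0.11, 0.22 and 0.45 at 1, 3 and 6 h, at percentiles 19.7, 89.1 and 96.5. With camera the adjusted p was 0.227, or 0.849 with an estimated correlation. Without the 1 h pair and with the preset correlation, it was 0.0206 in camera. Without the 3 h pair it was 0.489, and without the 6 h pair 0.506. TUB genes (5 measured) had medians of 0.52 at 3 h and 0.33 at 6 h, with TUB6 past the size rule at both times.

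BGLU45 and the peroxidase gene AT4G26010 were past the size rule at 3 and 6 h. HCT, CCR2 and the 4 measured genes of the laccase and peroxidase list were not. All 4 were peroxidase genes. No laccase of that list had a named probe set, so its laccases were not analysed here. HCT, an enzyme of monolignol synthesis, had log2 ratios of 0.02, 0.68 and 0.29, and CCR2 0.43, 0.17 and 0.73. Of the 4 peroxidase genes of the list at 3 h, AT5G64120 was at -1.54, PRX52 at -0.53, AT5G51890 at -0.43 and AT5G66390 at 0.01. Their median of -0.48 at 3 h (percentile 0.81) was 0.0079 without the array lacking DEX at 3 h. Of 3 flavonoid genes 0 were past the rule, with a list median of 0.77 at 3 h at percentile 98.6, which was 0.24 without the array lacking DEX at 3 h; DFR was at 0.77, UGT78D2 at 0.87 and BAN at 0.20. AT5G66120, of the shikimate pathway, was at 0.55 at 3 h.

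COB, needed for oriented cellulose deposition, was at -0.21, 0.10 and 0.19. The expansin gene EXPA8 was at -1.11 at 3 h and -1.63 at 6 h, inside the range of the arrays without DEX. The photosynthesis genes LHCB4.1 and RCA were at -0.40 and -0.50 at 6 h. The clock gene GI was at 0.41, 0.70 and 0.18, and the phloem sugar transporter SWEET11 at 0.07, 0.32 and -0.30. PDF1.2, a defensin, was 2.03-fold higher at 1 h and within the range later; PDF1.2b was at 0.60, 0.17 and 0.93. The guard cell lineage genes FMA, SPCH and MUTE were at 0.16, 0.52 and 1.32 at 6 h, with MUTE reading 66.3 against 7.27. Their median was -0.15 at 1 h, -0.51 at 3 h and 0.52 at 6 h, at percentiles 32.2, 4.98 and 83.7. None had a positive ratio at 1 or 3 h.

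Among reference genes, PEX4 was at 0.08, 0.02 and 0.15, AT2G28390 at -0.17, 0.06 and 0.06, and AT4G34270 at -0.35, 0.35 and -0.42. The list's median was 0.06 at 6 h and -0.10 after median centring. None of the 5 fixed lists with at least 3 measured genes passed camera's threshold on the common effect.

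The arrays without DEX show how leaves differed over 6 h with no inducer. COR27, a cold-regulated gene, was 31.1-fold higher at 6 h than at 0 h, AT1G07050 18.3-fold and AT2G23910 15.2-fold. AT5G35970, AT1G76240 and AT1G20030 were lowest, with log2 ratios of -4.00, -4.06 and -4.19. COR27 and AT2G23910 read 4.12 and 1.09 at 0 h and AT1G20030 3.37 at 6 h, below the medians of the bacterial control probe sets on those arrays (4.52 and 5.84), so the offset sets the sizes and ranks of these ratios. At least 2-fold over 0 h were 597 probe sets higher and 406 lower at 1 h, 1087 and 623 at 3 h, and 511 and 446 at 6 h. Time of day and differences between arrays are not separable in this course.

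The array without DEX at 3 h held the highest signals of STZ and WRKY53. STZ, a zinc finger repressor induced by stress, read 9738 there against 76.8 to 844.2 on the other 3 arrays without DEX and 1034 with DEX at 3 h. WRKY53, a senescence and defence regulator, read 4035 there against 92.9 to 338.6 and 372.1. The log2 ratios of these genes with DEX at 3 h were therefore -3.20 and -3.33, while both values with DEX lay above the lowest of the arrays without DEX.

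**Figure D3:**
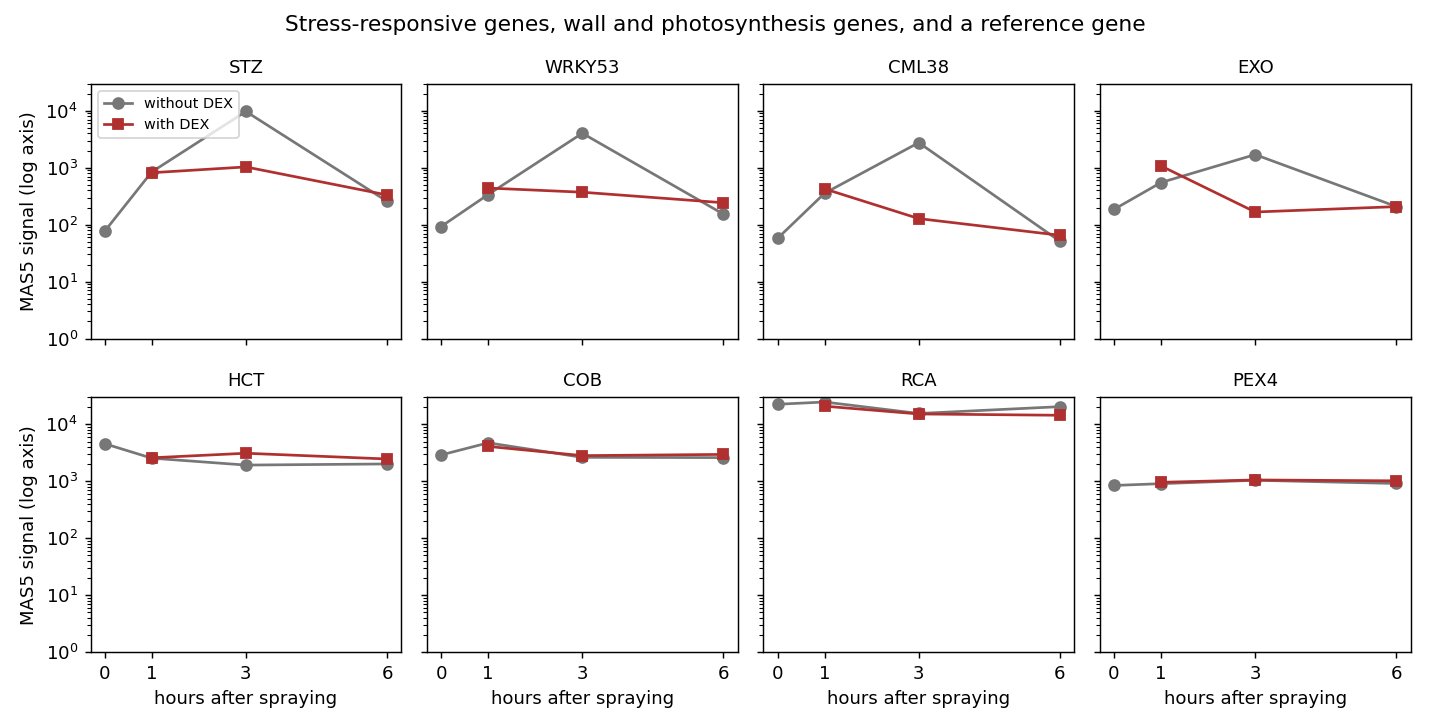
MAS5 signal on a log axis against hours after spraying for 8 named genes, with grey circles for arrays without DEX and red squares for arrays with DEX; each point is 1 array. STZ reads 9738 without DEX at 3 h and at most 1034 on every other array, while the reference gene PEX4 stays between 848 and 1060.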

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

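The results below stood out by rules set beforehand; no group had the 4 samples needed to look for a single outlying sample. Tests of the 3 h array without DEX and of the 6 h array with DEX were chosen only after those values were seen.

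AT3G44630 was higher with DEX at 1 h, with a log2 ratio of 1.67, and lower at 3 h, with -1.90. AT4G34150 was also higher at 1 h, with 1.16, and lower at 3 h, with -2.97. These are opposite directions at different times, and the difference was not tested. The array without DEX at 3 h held the highest no-DEX signal of both genes, 1257 for AT3G44630 against 398.4 at 1 h, and 4559 for AT4G34150 against 2292. Against the mean of the other 3 arrays without DEX, the log2 differences at 3 h were -0.74 and -0.91.

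Bacterial control probe sets, which have no target in leaf RNA, gave a median signal of 12.9 on the DEX array at 6 h, a signal outside the main measurement, against 4.52 to 6.61 on the other 6 arrays. Probe sets below the median on all 4 arrays without DEX had a median log2 ratio of 0.16 at 6 h, against 0.04 at 3 h and -0.0052 at 1 h. Of the 448 probe sets higher at 6 h, 195 were such dim ones. A raised background on that array is therefore a candidate explanation for small gains of dim probe sets at 6 h. No biological explanation was tested, and 1 array cannot separate the array from the treatment.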

How the results depend on the processing

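Leaving out the array without DEX at 3 h was chosen after seeing the data; the other alternatives were set before. At 3 h, the counts of 656 higher and 213 lower were 409 and 139 with the median of all signals as offset, 380 and 139 with a filter at the 75th percentile, 1460 and 477 at 1.5-fold and 309 and 85 at 3-fold. The lower count at 3 h was 750 with no range condition and 487 against the 0 h array. At 6 h, 448 higher and 120 lower became 243 and 51 with the median offset, 1125 and 211 with no filter, 1005 and 478 at 1.5-fold and 202 and 20 at 3-fold. At 6 h the higher count was 212 with the 75th percentile filter, and the lower count 221 after median centring, 450 against the 0 h array and 378 against the mean of the 4 arrays without DEX. At 1 h, 124 and 46 became 61 and 12 with the median offset, 280 and 190 with no filter, 81 and 22 with the 75th percentile filter, 413 and 424 at 1.5-fold, 31 and 5 at 3-fold, 289 and 99 with no range condition, 455 and 162 against the 0 h array, and 322 and 123 against the mean of the arrays without DEX. The lower count at 1 h was 87 with no offset, and the higher count 254 without the array lacking DEX at 3 h. The filter, fold and range settings change how many probe sets can pass; for the other settings the cause was not tested.

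For the common effect, limma's count of 0 higher became 1 with no replicate block (no time block), 2 with the 0 h array added and no time block, 2 with a prior that depends on the mean, and 0 to 103 with each time pair left out; the 0 lower became 0 to 6 with a pair left out. The 103 and 6 arose without the 1 h pair, and 1 higher without the 3 h pair. For the effect growing with hours, 0 higher became 14 with no time block and 46 with the 0 h array added, where 3 were lower. The cause was not tested.

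The xylan median of 2.28 at 3 h was 1.73 with the median offset and 2.05 without the array lacking DEX at 3 h; the 1.76 at 6 h was 2.99 with no offset, 1.49 with the median offset and 1.61 after median centring. The median of co-expressed loci, 0.22 at 3 h, was 0.65 with no offset and -0.0023 against the mean of the arrays without DEX; the 0.45 at 6 h was 1.16 with no offset, 0.20 with the median offset and 0.22 after quantile normalisation. In camera with the preset correlation, 0 lists passed; 1 did with no time block (xylan synthesis, adjusted p 0.0243) and 0 to 2 with a pair left out. The 2 were xylan synthesis (7.0e-04) and the co-expressed loci (0.0206), both without the 1 h pair. With an estimated correlation, on all 3 pairs, both lists had 0.849; the xylan adjusted p reached 0.354 with another pair left out. The cause was not tested.

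The alternatives were run for the genes named by the highest and lowest ratios at each time. These kept their direction in all 256 comparisons, 63 of which moved by more than the spread between arrays without DEX. Of 361 for the other list medians, 40 moved so. The named genes had been chosen as at least 2-fold different and outside the range of all 4 arrays without DEX. No mean of those arrays could therefore reverse their direction, and the kept direction is not evidence of robustness. The alternatives for MYB46 were not run, as it had no named probe set. STZ and WRKY53 were not among the genes run: relative to the mean of the other 3 arrays without DEX they were 1.82 and 0.98 log2 units higher with DEX at 3 h, opposite in direction to their ratios against the array of the same hour. The medians at 3 h of the laccase and peroxidase list, -0.48, and of the flavonoid list, 0.77, were -0.02 and 0.28 against the mean of the 4 arrays without DEX. NCRK, AT3G45710, BGLU45, AT4G26010, AT1G64405, IRX15, BAN, MUTE and AT5G66390 lay below the offset of 32 on every array without DEX, so the offset sets the size of their ratios. For AT4G26010 the log2 ratio of 4.40 at 3 h was 8.93 with no offset and 2.38 with the median offset.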

Other observations

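Calmodulin-like genes marked the array without DEX at 3 h. CML38 read 2760 there against 51.1 to 357.5 on the other 3 arrays without DEX, CML37 582.3 against 1.24 to 36.4, and the tetraspanin gene TET8 9779 against 1133 to 1330. The median of 7 CML genes on this array was 1.39 log2 units above 0 h. With DEX at 3 h the CML median was -0.50, at percentile 0.63 of random lists, but 0.02 without the array lacking DEX at 3 h. These genes, like AT2G22880 (1615 against 1.68 to 116.8) and AT4G27280 (12519 against 338.1 to 520.7), were chosen after their values were seen.

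Other gene families showed few members past the size rule. Of 47 UGT genes, 1 was higher at 3 h and 1 at 6 h. Of 29 SCPL genes 2 were higher at 3 h and 1 at 6 h, and of 22 TBL genes 1 was higher and 2 lower at 3 h. Of 20 BGLU genes BGLU45 was higher at both times, of 15 GH9 genes 2 were higher at 3 h, and of 14 expansins EXPB3 was higher at 6 h. Of 9 XTH genes XTH19 and of 15 IQD genes IQD22 (log2 ratio 1.00) were higher at 1 h. Among 14 SWEET, 11 GSTU, 15 TET and 7 CML genes, and among 43 plastid-encoded and 14 mitochondrion-encoded genes, 0 were past the rule at any time. Median log2 ratios at 6 h were -0.0099 for UGT, 0.0019 for SCPL, 0.01 for TBL, 0.32 for BGLU, 0.25 for GH9, -0.01 for expansins, 0.20 for XTH, 0.13 for SWEET, -0.20 for GSTU, 0.13 for TET, 0.14 for IQD, 0.07 for CML, 0.04 for plastid and 0.29 for mitochondrial genes. The medians of SCPL, TBL, SWEET, TET, IQD, CML and plastid genes turned negative after median centring, and against the mean of the 4 arrays without DEX the medians were 0.26 for GSTU, -0.06 for XTH, 0.14 for expansins, -0.20 for CML and -0.06 for plastid genes, each of the opposite sign. Median centring shifts all ratios at 6 h alike, moving the median of the tested probe sets from 0.01 to -0.15. The signs at 6 h of the medians named here as turning therefore depend on the processing.

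The tests of the sharing between 3 and 6 h and of the other divisions of the arrays were set before their results were seen; those of the sharing of dim probe sets and of the 3 h array without DEX were chosen after. The sharing of higher probe sets between 3 and 6 h, which includes GUT1, IRX15-L and BGLU45, did not rest on the arrays without DEX that both times use: with no such array in common, 274 were shared, 13.7 times the number expected of independent lists. This argues against the shared arrays as the whole cause. Of the 262, 55 were above the 75th percentile on an array without DEX, where noise of dim signals is small, 28.0 times the expected number; for these, GUT1 and TUB6 included, the value argues against such noise. For the other 207, which include IRX15-L and BGLU45, noise was not settled. Of these, 119 were at least 3-fold higher at both times and 88 were not. By the fold rule alone, each time against its own array without DEX, 236 dim probe sets were higher at 3 and 6 h. This was 9.44 times the 25 that 1 h shared with either. At 1 h only 289 probe sets were at least 2-fold higher, against 737 at 3 h and 488 at 6 h. Fewer could therefore be shared with 1 h, and these counts do not decide whether noise accounts for the sharing of dim probe sets. Pairs of arrays without DEX, set against the other 2 of different hours, shared 1 to 181 such probe sets, and at 3-fold 0 to 74 against 129 with DEX, so arrays of different hours can share many as well; the comparisons with DEX were made within the hour. A response to MYB46 that builds up after 1 h was not tested and stays open, as does a direct effect of DEX on leaves, since no DEX-treated plants without the construct were used here.

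Of the 750 probe sets at least 2-fold lower with DEX at 3 h, as STZ, WRKY53, CML38 and EXO were, 107 (14.3%) stayed so against the mean of the other 3 arrays without DEX; at 1 h it was 20.2% of 99 and at 6 h 61.8% of 152. Choosing low ratios favours a high comparator, so these shares do not decide how much rests on the array without DEX at 3 h. In 767 of the probe sets tested at 3 h, that array was highest and at least 2-fold above the mean of the other 3. By the same rule, the arrays without DEX at 1 and 6 h led in 367 and 232 of those tested at their own hours. Time of day alone is argued against: in these probe sets the DEX array of the same hour lay 0.45 log2 units above the other 3, against 1.84 for the array without DEX, a share of 0.247. Probe sets chosen in the same way at 1 and 6 h kept shares of 0.917 and 0.872, and the share at 3 h was 0.284 times the lower of these. Degraded RNA is argued against too, since the ratio of 3' to 5' GAPDH signal was 1.42 there and 1.57 to 2.03 on the other arrays. Handling of those plants, and a dampening of a spray or wound response by DEX or MYB46, may each account for the high signals on that array and were not tested.

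Dividing the 6 arrays of 1, 3 and 6 h into 3 and 3 in other ways gives 10 divisions, too few for a share under 0.05. For the common effect, limma gave 933 probe sets at an unadjusted p under 0.05 with the real division and at most 1600 with another; 4 of the 10, the real one included, gave as many. For the effect growing with hours the real value was 1226 and the highest other 1600, and again 4 of the 10 gave as many. The division that exchanged only the 1 h pair, and so kept 3 and 6 h alike, gave 1571 and 1379; the other 2 parted only the 3 h pair.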
